A study of Homo sapiens with 6 samples.

How the data were processed

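RNA from 3 cultures of PANC1 cells and 3 cultures of PANC1OR cells was sequenced, 1 library per culture, and each library is a column of 1 deposited count table. PANC1 is an established human cell line from a carcinoma of the pancreatic duct. PANC1OR is a subline that the submitters obtained by growing PANC1 in rising concentrations of oxaliplatin, a platinum drug that forms adducts on DNA. The series design text describes the cultures as triplicates of each line, so p-values measure the spread between cultures of 1 parental and 1 resistant line, not between independently derived resistant lines. The labels name a library kit for messenger RNA. The series design text calls the resistant state stable without the drug, and whether the drug was present at harvest is not given in the sources used here.

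The values are read counts per gene, deposited by the authors without normalization. Per the submitters' processing notes and the series design text, read quality was inspected with FastQC 0.11.5, adaptors were trimmed with cutadapt through Trim Galore 0.4.2, reads were aligned to GRCh38 with STAR 2.5 and counted with featureCounts of Subread 1.6.2. The series design text also names edgeR 3.24.3 with TMM factors and a likelihood ratio test for the authors' own comparison, with cutoffs of an absolute log2 fold change over 2 and a false discovery rate under 0.01. The release of the gene annotation, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner therefore cannot be told apart, and values of near-identical gene copies are uncertain. The table held 5 further columns without values.

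The table has 58735 gene rows with Ensembl identifiers, of which 44225 carry a symbol. GENCODE release 44 on the same genome build was used for positions, gene classes, exon length and the GC content of the longest transcript of a gene, matched by identifier. It held 58207 of the identifiers and 18638 of the 18751 tested ones. Positions are 1-based GRCh38 coordinates from that release and may differ slightly from the authors' annotation.

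Library totals were 15660171, 10199268 and 15875431 reads for PANC1 replicates 1 to 3, and 26394388, 15702042 and 12623721 reads for PANC1OR replicates 1 to 3. A group without reads of a gene was given a floor of 3 reads over the group, which is 0.0715 CPM (counts scaled to the TMM-adjusted library total) in PANC1 and 0.0547 CPM in PANC1OR. A fold against a group with 0 reads is a lower bound from that floor, and a ratio against a group with 1 to 3 reads carries an exact 95% counting interval. Such bounds and intervals cover counting error only.

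Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 18751. Libraries were scaled with TMM factors and the lines compared with edgeR's quasi-likelihood F test on all 6 libraries, without covariates. This test replaced the likelihood ratio test of the authors, which was kept as an alternative. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and the cutoffs of the series design text were applied to the same fit. Adjusted p-values of genes come from this fit unless another is named. Log2 fold changes are PANC1OR minus PANC1 and are given with the standard error derived from the F statistic. Levels are CPM as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.281 and the median log2 fold change of all tested genes 0.04.

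A set of 40 gene lists was tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. The self-contained test fry was also run. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members are counted as risen or fallen by the adjusted p over all tested genes, and a second count was adjusted over the list alone. Genes were also grouped into blocks of 50 consecutive tested genes along each chromosome and tested with camera in the same way.

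Genes were named by a rule. It took the 10 highest and 10 lowest log2 fold changes among called protein-coding genes with a mean of at least 5 CPM and no overlap between the lines' libraries, up to 4 members of each list with the smallest p-values and a mean of at least 1 CPM, and 14 fixed genes of platinum handling, DNA repair, epithelial and mesenchymal state and growth. Members outside this rule were named where they complete a small count, after their values were seen. The samples' groups, the tests of genes, lists and chromosome blocks, the lists and the naming rule were set before the data were examined, as were the alternatives except those named below as added later. Tests of explanations chosen later are named in the closing section.

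The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and no factors; no low-count filter and a filter at over 1 CPM in 3 libraries; edgeR's likelihood ratio test, DESeq2's Wald test, limma-voom, an adjusted p under 0.01 and a test against a 1.5-fold change; the removal of each library in turn; and the replicate number as a block. After the libraries had been inspected, gene-wise offsets were added that remove each library's trend with GC content (lowess, span 0.3) or with GC content and exon length (mgcv 1.9.3), and PANC1 replicate 2 and PANC1OR replicate 3 were left out together. For the chromosome blocks, the GC offsets and the removal of PANC1OR replicate 3 were likewise added then, beside blocks of 100 genes and an estimated correlation, which were planned.

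The procedure was tested on simulated counts with the means, library sizes and dispersions of these libraries, in which 100 genes were changed by a log2 fold change of 1 and 100 by 2. Of 18255 genes tested in the simulation of this comparison, 111 were called, which included 89% of the genes changed by 2 and 11% of those changed by 1, and 9.91% of the calls were false. With a simulated GC trend in PANC1OR replicate 3, recovery fell to 18% and 0%, and GC offsets returned it to 76% and 9%. The dispersions came from the real libraries and so already held the real GC trend as noise, with the simulated trend on top. These shares therefore do not give the recovery in the real data. A list whose members were changed by a log2 of 0.7, 1 of 40, was recovered with a camera adjusted p of 4.32e-18, and 0 other lists were called. With an estimated correlation its adjusted p was 0.0215, again with 0 others called. The simulated genes were drawn independently of each other, so lists with correlated members were not covered.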

Results

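Gene expression was measured by RNA sequencing in 3 cultures of PANC1, a human pancreatic ductal carcinoma line, and in 3 cultures of PANC1OR, its oxaliplatin-resistant subline. The libraries held 10199268 to 26394388 reads assigned to genes, and between 27848 and 31939 genes had at least 1 read in a library. The single comparison of the design asks which genes differ in level between the resistant line and the untreated parental line.

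The genes with the highest log2 fold changes in PANC1OR were nearly silent in PANC1. FAM83B, which encodes an adaptor of EGF receptor and RAS signalling, had 0 reads in PANC1 and 36.3 ± 13.9 CPM (SD, n = 3) in PANC1OR, at least 509-fold higher. TRPA1, an irritant-gated cation channel, rose from 0.269 ± 0.0744 to 249.9 ± 75.3 CPM, a log2 fold change of 9.85 ± 0.42 (SE; adjusted p = 1.09e-05). PELI2, an E3 ubiquitin ligase of Toll-like receptor signalling, rose by 9.78 ± 0.36, DHRS9, a retinol dehydrogenase, by 8.14 ± 0.28, and HGF, the ligand of the MET receptor, by 7.67 ± 0.56 on the same scale, with PANC1 replicate 3 at 0.612 CPM and replicates 1 and 2 at 0.1245 and 0.1044. SRGN, a secreted proteoglycan, had 3 reads in PANC1 and 2227 in PANC1OR, a ratio of 568 (95% counting interval 194 to 2756), and TRIML2 had 1 and 884 reads. The remaining members of the 10 highest were the cancer-testis genes MAGEA12 (at least 160.1-fold), CSAG1 (at least 157-fold) and MAGEA6 (1 read against 555). The MAGEA genes are near-identical copies, so the split of reads between them is uncertain.

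The genes with the lowest log2 fold changes included an adhesion molecule, a growth factor binding protein and a phosphatase. MXRA5, a matrix remodelling gene, fell from 34.0 ± 3.46 CPM to 3 reads in PANC1OR, a ratio of 633 (216 to 3073). SORBS2 and SH3RF3, both SH3-domain scaffolds, had 1 read each in PANC1OR against 586 and 437 in PANC1. PTPN13, a protein tyrosine phosphatase, fell from 83.4 ± 10.3 to 0.305 ± 0.0483 CPM (log2 fold change -8.05 ± 0.28, adjusted p = 8.17e-06). IGFBP2, which binds insulin-like growth factors, stood at -7.67 ± 0.74, with PANC1OR replicate 3 at 0.826 CPM and replicates 1 and 2 at 0.112 and 0.0625, and CDH2, which encodes N-cadherin, at -6.27 ± 0.32. The others were ZNF354C (-7.03 ± 0.41; PANC1OR replicate 2 at 0.2498 CPM, replicates 1 and 3 at 0.0748 and 0.0826), SIRPA (-6.01 ± 0.25), BEND7 (-5.99 ± 0.55) and ZNF488 (-5.88 ± 0.42). By the adjusted p these 20 genes were also called in each fit without 1 library. FAM83B (ENSG00000168143) lies on chromosome 6 at 54846771 to 54945099, TRPA1 (ENSG00000104321) on chromosome 8 at 72019917 to 72075584, PELI2 (ENSG00000139946) on chromosome 14 at 56117814 to 56301524, MXRA5 (ENSG00000101825) on chromosome X at 3308565 to 3346652 and PTPN13 (ENSG00000163629) on chromosome 4 at 86594315 to 86815171. TRPA1, PELI2 and PTPN13 overlap a gene on the opposite strand, whose reads cannot be separated here.

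**Figure D1:**
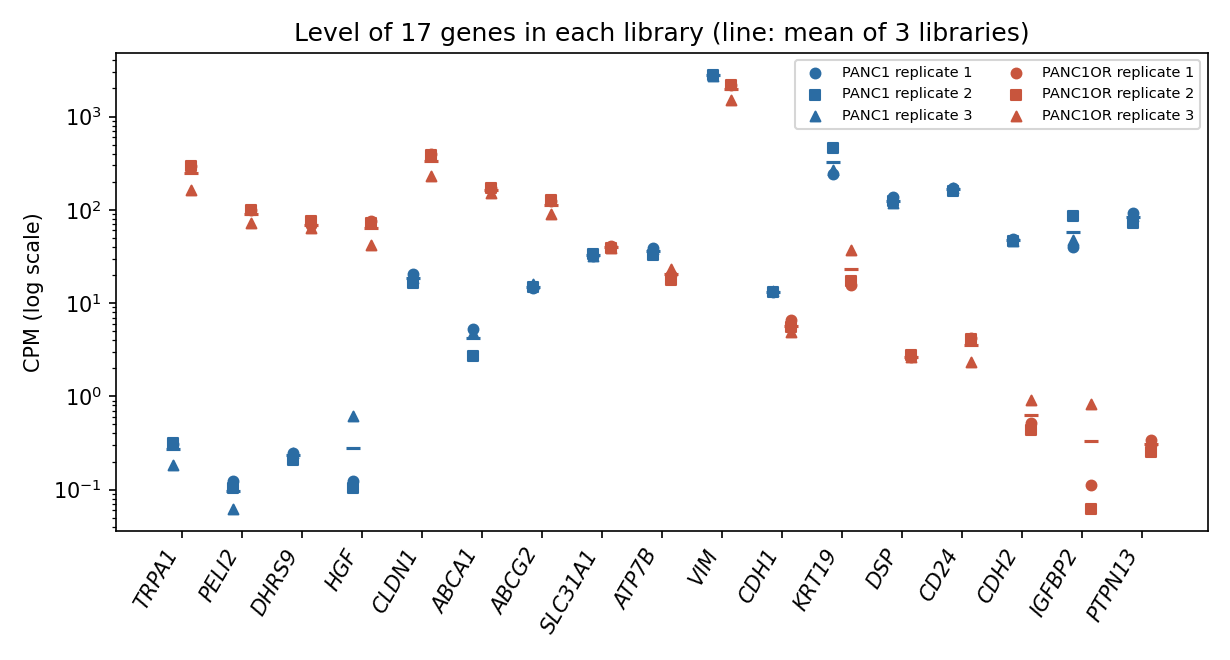
CPM of 17 named genes on a logarithmic axis in each of the 6 libraries, with PANC1 in blue, PANC1OR in red, marker shapes for the replicate number and a short line at the mean of 3 libraries. TRPA1 lies below 0.32 CPM in the 3 PANC1 libraries and above 160 CPM in the 3 PANC1OR libraries, while SLC31A1 lies between 31.6 and 40.6 CPM in the 6 libraries.

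Across all 18751 tested genes, 1939 were higher and 1406 lower in PANC1OR by edgeR's quasi-likelihood test, of which 1481 and 1088 were protein-coding. The called share was 17.8% of all tested genes and 19.7% of the protein-coding ones. With the cutoffs of the series design text, 699 genes were higher and 473 lower, 1172 in all. Of these, 890 were protein-coding, where the series design text gives 1342, and the likelihood ratio test that the text names gave 1335 genes, 980 of them protein-coding. The first count depended on single libraries: 8663 genes passed without PANC1OR replicate 3, 1920 without PANC1 replicate 1 and 1821 without PANC1 replicate 3. All 3345 genes called with 6 libraries were called in the same direction without PANC1OR replicate 3. That fit tested 19650 genes, so its counts in the lists below stand beside a larger share of calls over all genes. The count past the cutoffs was 708, 735 and 681 without PANC1 replicates 1, 2 and 3.

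The lines separated on the first principal component, which held 65.6% of the variance. PANC1OR replicate 3 stood apart from replicates 1 and 2 on the second, which held 25.2%. The SD of log2 differences over genes was 0.28 between PANC1OR replicates 1 and 2, and 0.93 and 0.96 between replicate 3 and these. In replicate 3, genes with over 60% GC were 1.37 higher in log2, by the median, than in replicates 1 and 2, and genes with under 40% GC had a median difference of -0.91. PANC1 replicate 2 deviated the same way to a smaller extent, with 0.37 and -0.19 against replicates 1 and 3. No pair of libraries agreed within sampling noise. The closest, PANC1OR replicates 1 and 2, had a chi-square of 3.59 per degree of freedom. With offsets for the GC trend of each library, 7307 genes were called, including 3335 of the 3345.

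**Figure D2:**
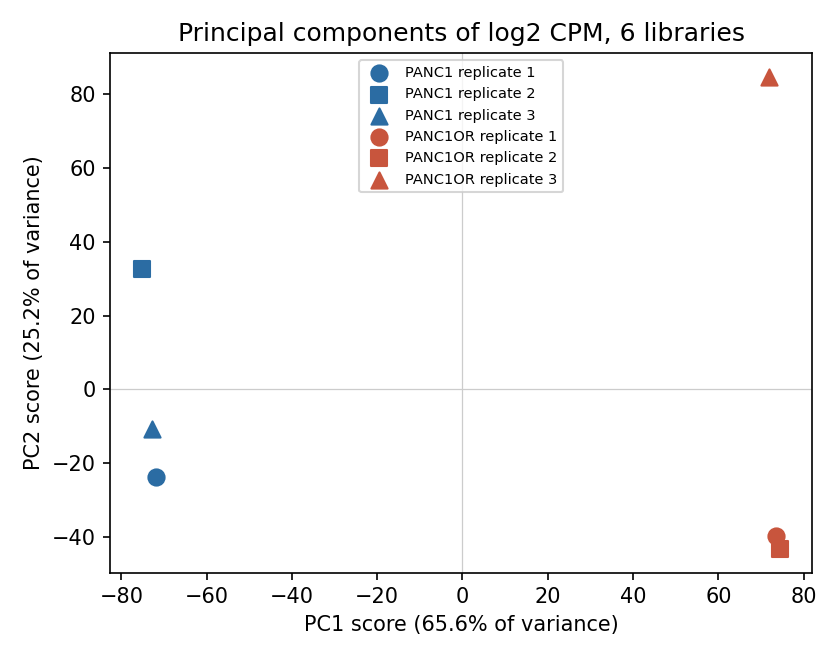
Scores of the 6 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis. The PANC1 libraries lie at -75.1 to -71.8 and the PANC1OR libraries at 72.0 to 74.4 on PC1, and PANC1OR replicate 3 lies at 84.7 on PC2.

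**Figure D3:**
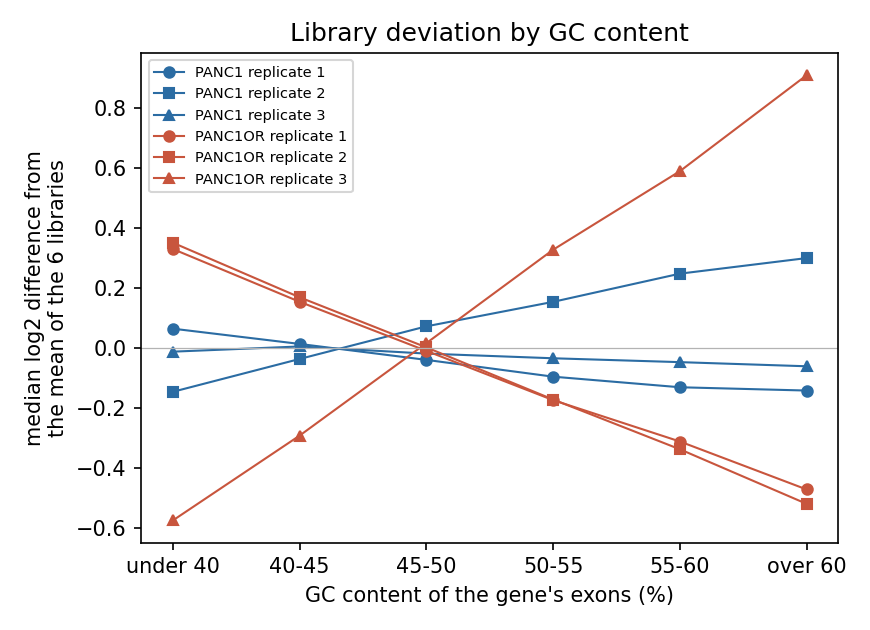
Median log2 difference of each library from the mean of the 6 libraries (vertical axis) over genes grouped by the GC content in percent of the exons of their longest transcript (horizontal axis), for 11490 genes with a mean of at least 5 CPM. PANC1OR replicate 3 goes from -0.58 in genes under 40% GC to 0.91 in genes over 60% GC, and PANC1OR replicates 1 and 2 go the other way.

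Genes of epithelial and mesenchymal state changed in both directions. DSP, which encodes the desmosomal protein desmoplakin, fell from 126 ± 10.3 to 2.67 ± 0.0696 CPM (-5.55 ± 0.21), KRT19, a ductal keratin, fell by 3.81 ± 0.43 on the log2 scale, and CDH1, which encodes E-cadherin, stood at -1.22 ± 0.22 (adjusted p = 0.00613). CLDN1, a tight junction claudin, rose from 18.5 ± 2.07 to 338 ± 92.7 CPM (4.19 ± 0.27), and OCLN, which encodes occludin, stood at -1.42 ± 0.21. Of the mesenchymal genes, CALD1, an actin-binding protein gene, rose by 3.78 ± 0.21, while MMP2, a gelatinase, stood at -4.08 ± 0.34 and S100A4, a calcium-binding protein gene, at -4.91 ± 0.46. VIM, which encodes vimentin, was at 2779 ± 45.3 CPM in PANC1 and 1954 ± 375 in PANC1OR (adjusted p = 0.132), and FN1, which encodes fibronectin, was at 12.1 ± 1.46 and 7.17 ± 1.91 CPM (adjusted p = 0.0906). Of 25 epithelial junction and keratin genes 6 rose and 6 fell (7 and 7 adjusted over the list alone), and of 23 mesenchymal markers and transcription factors 4 rose and 6 fell (4 and 9 adjusted over the list alone). Neither list passed camera, with adjusted p of 0.705 and 0.114. Without PANC1OR replicate 3, 7 and 8 of the epithelial and 6 and 10 of the mesenchymal genes rose and fell.

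Genes of the extracellular matrix and its receptors also split. Counts without PANC1OR replicate 3 were 7 risen and 9 fallen collagens, 7 and 7 proteases and inhibitors (11 and 4 with GC offsets), and 6 and 6 integrins. Among collagens, COL11A1 (-3.18 ± 0.18) fell, and COL21A1 (3.65 ± 0.27), COL6A3 (3.56 ± 0.28) and COL5A2 (1.69 ± 0.17) rose, 5 up and 5 down of 21 (7 and 7 adjusted over the list alone). Some laminin chain genes rose: LAMA4 from 0.504 to 31.7 CPM (5.96 ± 0.27) and LAMB1 by 2.22 ± 0.16, while NID1, which encodes nidogen, stood at -0.69 ± 0.18. The list of laminins and other basement membrane genes (3 rose and 1 fell of 12, also adjusted over the list alone) was called higher, with a camera adjusted p of 0.0318, and lost this call at an adjusted p of 0.918 with an estimated correlation. Its balance turned to 3 risen and 7 fallen without PANC1OR replicate 3 and was 3 and 3 with GC offsets, which also ended the call (0.0633). It lost the call without PANC1 replicate 1, 2 or 3 (0.145, 0.174 and 0.0579) and without PANC1OR replicate 1 or 3 (0.0514 and 0.443), and the adjusted p of NID1 was 0.0572 to 0.145 without any 1 library other than PANC1OR replicate 3. Of 26 matrix proteases and inhibitors 5 rose and 4 fell, the same adjusted over the list alone, with MMP1 (3.45 ± 0.33) and the urokinase receptor gene PLAUR (2.37 ± 0.33) among the risen and ADAMTS4 (-3.68 ± 0.39) among the fallen. Of 14 integrins 4 rose and 3 fell (6 and 5 adjusted over the list alone), with ITGB8 at -4.01 ± 0.39 and ITGB4 at -2.69 ± 0.40 (38.8 CPM in PANC1OR replicate 3, 16.4 and 13.1 in replicates 1 and 2).

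Genes that carry platinum drugs or copper had 2 calls among 14 with 6 libraries, beside 17.8% of all tested genes. They had more without PANC1OR replicate 3, as did all tested genes together. The copper importer gene SLC31A1 was at 32.6 ± 1.14 CPM in PANC1 and 39.6 ± 0.870 in PANC1OR (0.28 ± 0.18, adjusted p = 0.341), and the copper exporter gene ATP7A at 42.5 ± 5.78 and 43.3 ± 13.5 CPM. ATP7B, the second copper-exporting ATPase gene, was lower in PANC1OR, at 20.4 ± 2.90 against 36.2 ± 3.32 CPM (-0.83 ± 0.21, adjusted p = 0.0265), but its adjusted p was 0.0508 to 0.126 without PANC1 replicate 1, 2 or 3 or PANC1OR replicate 1 or 2. Of the 14 genes of this list 0 rose and 2 fell (0 and 3 adjusted over the list alone). Among 12 ABC transporter genes only ABCA1, a cholesterol exporter gene, and ABCG2, a multidrug exporter gene, rose, from 4.24 to 164 CPM (5.25 ± 0.29) and from 15.04 to 114 CPM (2.92 ± 0.21), also adjusted over the list alone. ABCC2, an exporter of glutathione conjugates, was at 3.51 ± 0.129 and 3.61 ± 0.204 CPM (adjusted p = 0.923). Without PANC1OR replicate 3, 1 rose and 7 fell of the first list and 3 rose and 3 fell of the ABC list. Neither list passed camera (adjusted p of 0.465 and 0.114).

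Genes of thiol metabolism moved both ways. GSTP1, a glutathione transferase gene, was at 210 ± 112 CPM in PANC1 and 151 ± 92.4 in PANC1OR (adjusted p = 0.574), and in both lines the library with the highest GC deviation had the highest level. MGST1, a microsomal glutathione transferase gene, rose by 3.05 ± 0.28, and the peroxidase genes GPX7 and GPX3 stood at -3.35 ± 0.34 and -2.60 ± 0.33. The glutathione list had 6 risen and 5 fallen of 28, the same adjusted over the list alone. Of 26 targets of the oxidant-responsive factor NRF2, 2 rose and 4 fell (3 and 4 adjusted over the list alone): SLC7A11, a cystine importer gene, rose by 1.78 ± 0.33, and TXNRD1, which encodes thioredoxin reductase, and PRDX1, a peroxiredoxin gene, stood at -1.13 ± 0.17 and -1.12 ± 0.17. Of 4 metallothionein genes tested, from 12 listed symbols, MT1A rose (2.24 ± 0.35), and 2 did so adjusted over the list alone. Camera called none of these 3 lists (adjusted p of 0.903, 0.465 and 0.288). Of the glutathione list 6 rose and 6 fell without PANC1OR replicate 3, of the NRF2 list 3 and 11, and of the metallothioneins 2 and 0.

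Few DNA repair genes were called with 6 libraries, beside 17.8% of all tested genes. The excision repair and translesion lists were close to that share. DNA repair genes had more calls without PANC1OR replicate 3, as did all tested genes together. The mismatch repair list had 0 calls among 9 genes by edgeR's test, over all genes or adjusted over the list alone. Of these 1 rose and 2 fell without PANC1OR replicate 3, and 0 rose and 5 fell with GC offsets. The nucleotide excision repair gene ERCC1 was at 68.0 ± 21.8 and 95.4 ± 34.1 CPM (adjusted p = 0.353). Of 24 genes of that pathway 2 rose and 2 fell (1 and 2 adjusted over the list alone), and of 34 Fanconi anaemia and homologous recombination genes 2 rose (0 adjusted over the list alone), UBE2T by 0.82 ± 0.19 and RAD51B by 1.00 ± 0.24. Of 12 translesion synthesis genes RAD18 rose by 1.34 ± 0.28 and POLN, a polymerase gene, stood at -1.13 ± 0.29, also adjusted over the list alone. Each of these UBE2T, RAD51B, RAD18 and POLN calls was lost without at least 1 library, such as without PANC1 replicate 3, where the adjusted p was 0.123, 0.117, 0.0545 and 0.113. Without PANC1OR replicate 3, 3 rose and 6 fell of the excision repair list, 11 and 10 of the Fanconi list and 3 and 3 of the translesion list. The mismatch repair and translesion lists had a mean GC of 43.0% and 42.4%, and in PANC1OR replicate 3 their medians stood at -0.68 and -0.69 in log2 from replicates 1 and 2.

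Apoptosis and p53 target genes showed single large changes. PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 4.10 to 24.4 CPM (2.58 ± 0.30), BCL2A1, an anti-apoptotic family member, rose by 1.56 ± 0.26 and BMF, a pro-apoptotic one, by 1.77 ± 0.35, while BCL2L11, which encodes pro-apoptotic BIM, stood at -1.29 ± 0.20. Of 17 BCL2 family genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.273). Of 27 p53 targets 3 rose and 2 fell (3 and 3 adjusted over the list alone), led by the polo-like kinase gene PLK2 at -3.55 ± 0.26 and the stress cytokine gene GDF15 at 2.94 ± 0.47 (275 CPM in PANC1OR replicate 3, 93.5 and 95.5 in replicates 1 and 2). CDKN1A, which encodes the cell cycle inhibitor p21, was at 11.02 ± 2.07 and 14.4 ± 4.88 CPM (adjusted p = 0.44). In the BCL2 list 8 rose and 3 fell without PANC1OR replicate 3, and in the p53 list 5 and 6.

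Of the genes of the integrated stress response 13 of 28 rose, and 14 did not pass. CHAC1, a glutathione-degrading enzyme gene, rose from 5.12 ± 1.81 to 61.3 ± 40.2 CPM (3.60 ± 0.50), with 107.7 CPM in PANC1OR replicate 3 and 35.5 and 40.8 in replicates 1 and 2. The asparagine synthetase gene ASNS rose by 1.97 ± 0.29, the serine synthesis gene PSAT1 by 1.03 ± 0.17 and EDEM1, a gene of endoplasmic reticulum protein degradation, by 1.33 ± 0.18. Of 28 ATF4 and unfolded protein response genes 13 rose and 1, the lipoprotein receptor gene VLDLR, fell (14 and 1 adjusted over the list alone); VLDLR was named after its value was seen, and its adjusted p was 0.0901, 0.114 and 0.0726 without PANC1 replicate 1, PANC1 replicate 3 and PANC1OR replicate 2. The split was less one-sided without PANC1OR replicate 3 (16 risen and 7 fallen) and with GC offsets (13 and 5). The list was called higher by camera (adjusted p = 0.037), and lost the call with an estimated correlation, at an adjusted p of 0.918, and without PANC1 replicate 1 (0.139), PANC1 replicate 3 (0.0659) or PANC1OR replicate 3 (0.0876). It was called with GC offsets (0.0047) and with PANC1 replicate 2 and PANC1OR replicate 3 left out together (0.0012). Of 14 heat shock protein genes the small chaperone gene HSPB8 rose from 1.36 CPM, with 2.298 in PANC1 replicate 2 and 0.934 and 0.856 in replicates 1 and 3, to 24.0 CPM, and 2 fell, also adjusted over the list alone, DNAJA1 at -0.82 ± 0.19 and HSP90AB1 at -0.71 ± 0.18. The adjusted p of DNAJA1 and HSP90AB1 reached 0.0745 and 0.126 without 1 library, and both stayed called only without PANC1OR replicate 3 among these fits, where 1 gene of the list rose and 6 fell.

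Of the interferon-stimulated genes some rose and some fell, and 15 of 27 did not pass. IFIT2 and IFIT3, which encode antiviral RNA-binding proteins, rose by 2.89 ± 0.27 and 2.57 ± 0.24, whereas MX2, a dynamin-like antiviral GTPase gene, fell from 59.2 to 3.65 CPM (-4.02 ± 0.22) and IFITM2, a membrane restriction factor gene with near-identical relatives, from 86.1 to 2.45 CPM (-5.18 ± 0.48; 4.21 CPM in PANC1OR replicate 3, 1.57 and 1.56 in replicates 1 and 2). Of 27 genes 10 rose and 2 fell (14 and 2 adjusted over the list alone), and camera called the list higher (adjusted p = 0.037). The call was lost with an estimated correlation, at an adjusted p of 0.918, and without PANC1 replicate 1 (0.139), PANC1 replicate 3 (0.0579) or PANC1OR replicate 3 (0.0876, with 15 risen and 3 fallen). GC offsets also ended it (0.125), as did leaving out PANC1 replicate 2 and PANC1OR replicate 3 together (0.159). In antigen presentation, the immunoproteasome genes PSMB8 and PSMB9 rose by 2.18 ± 0.39 and 1.84 ± 0.38 and the peptide-trimming gene ERAP2 by 1.73 ± 0.31; HLA-F, named after its value was seen, completed 4 risen and 0 fallen of 15, the same adjusted over the list alone (camera adjusted p = 0.165). The adjusted p of PSMB9 was 0.0681 and 0.0735 without PANC1 replicates 1 and 3, and that of HLA-F 0.052 to 0.149 without any 1 library other than PANC1OR replicate 3, without which 6 genes of the list rose and 0 fell.

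Several inflammatory chemokine genes were lower in PANC1OR, while 10 of the 16 genes of their list did not pass. CCL2, a monocyte chemoattractant gene, fell from 99.5 to 5.03 CPM (-4.30 ± 0.27), the neutrophil chemokine gene CXCL1 from 14.3 to 0.758 CPM (-4.17 ± 0.29) and TNFAIP3, which encodes the NF-kappaB inhibitor A20, stood at -1.57 ± 0.24, while the adhesion molecule gene ICAM1 rose by 1.88 ± 0.24. Of 16 NF-kappaB and cytokine genes 1 rose and 5 fell (3 and 7 adjusted over the list alone), the other fallen ones being CXCL8 and CCL5, which were named after their values were seen. Camera called the list lower (adjusted p = 0.0221). The call was lost with an estimated correlation, at an adjusted p of 0.657, and without PANC1OR replicate 3, at 0.0876 with 3 risen and 7 fallen. GC offsets also ended it (0.125), as did leaving out PANC1 replicate 2 and PANC1OR replicate 3 together (0.0783).

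Targets of 3 signalling pathways changed without a common direction. Among YAP and TAZ targets ANKRD1 rose by 2.66 ± 0.20, while the forkhead factor gene FOXF2 stood at -4.79 ± 0.30 and the matricellular gene CCN2 at -1.56 ± 0.17, 4 up and 5 down of 21 (4 and 8 adjusted over the list alone). Among TGF-beta targets the latent TGF-beta binding protein genes LTBP1 and LTBP2 went opposite ways (3.30 ± 0.19 and -3.90 ± 0.32), with 2 up and 5 down of 18 (3 and 5 adjusted over the list alone). Of 10 canonical Wnt targets 3 rose, TNFRSF19 (2.53 ± 0.33), the Wnt inhibitor gene DKK1 (1.36 ± 0.17) and the cyclin gene CCND1 (1.06 ± 0.16), and 1, RNF43, fell, which was named after its value was seen (3 and 2 adjusted over the list alone). Without PANC1 replicate 3 the adjusted p of RNF43 was 0.0551. None of these 3 lists passed camera (adjusted p of 0.365, 0.707 and 0.707). The numbers risen and fallen without PANC1OR replicate 3 were 5 and 9 (YAP), 4 and 8 (TGF-beta) and 3 and 5 (Wnt).

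Some genes of cholesterol synthesis were lower in PANC1OR, and 17 of 23 did not pass with 6 libraries. SQLE, the squalene epoxidase gene, and INSIG1, a sterol sensor gene, stood at log2 fold changes of -1.03 ± 0.19 and -1.02 ± 0.19. Of 23 genes 0 rose and 6 fell, also adjusted over the list alone, and camera called the list lower (adjusted p = 0.0095). The list stayed called without each library in turn (0.000156 to 0.0149), and without PANC1OR replicate 3, where 20 of its genes fell, but not with an estimated correlation, where the adjusted p was 0.657. INSIG1 had an adjusted p of 0.0503 without PANC1 replicate 3. Among 32 hypoxia and glycolysis genes 5 rose and 2 fell, also adjusted over the list alone, and 7 and 7 did so without PANC1OR replicate 3, with the hexokinase gene HK2 at 3.05 ± 0.21, the enolase gene ENO2 at 1.85 ± 0.28 and ANGPTL4, which encodes a lipase inhibitor, at 2.75 ± 0.48 (144.3 CPM in PANC1OR replicate 3, 48.5 and 48.2 in replicates 1 and 2). The oxygen sensor gene EGLN3 had 96 reads in PANC1 and 3 in PANC1OR, a ratio of 41.8 (13.9 to 206).

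Proliferation and core machinery genes had few calls with 6 libraries, beside 17.8% of all tested genes. They had more without PANC1OR replicate 3, as did all tested genes together. MKI67, a marker of cycling cells, was at 1328 ± 193 CPM in PANC1 and 1198 ± 74.2 in PANC1OR (adjusted p = 0.654). Of 33 mitotic genes 1 rose and 3 fell (0 and 3 adjusted over the list alone), with the kinesin gene KIF20A at -0.94 ± 0.18 and an adjusted p of 0.0502 without PANC1OR replicate 1. Of 41 S phase genes 1, the replication factor gene GINS3 (1.19 ± 0.20), rose and 3 fell (1 and 2 adjusted over the list alone); without PANC1OR replicate 3, 5 rose and 19 fell. By edgeR's test 1 of 41 ribosome biogenesis factors, RRS1, rose (0 adjusted over the list alone), and 2 of 45 nuclear genes of oxidative phosphorylation, COX5A and ATP5MC1, fell (0 adjusted over the list alone). The adjusted p of RRS1, COX5A and ATP5MC1 reached 0.158, 0.113 and 0.134 without 1 library. Over all genes and adjusted over the list alone, 0 of 57 cytosolic ribosomal protein genes, 0 of 13 mitochondrially encoded genes and 0 of 15 histone genes passed. Without PANC1OR replicate 3 these 3 lists had 1 risen and 7 fallen, 1 risen, and 3 fallen genes, the mitotic list 7 and 9, ribosome biogenesis factors 4 and 13 and oxidative phosphorylation 1 and 11. When PANC1 replicate 2 was left out too, 23 ribosomal protein genes rose and 13 fell, and 10 mitochondrially encoded genes rose. None of the 7 lists passed camera.

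Markers of pancreatic and other cell types were largely low or mixed. Of the listed symbols, 10 of 24 ductal, 3 of 25 acinar and endocrine and 12 of 19 stem cell markers were among the tested genes. So were 8 of 20 neuronal, 7 of 17 fibroblast and 6 of 19 leukocyte and endothelial ones. A gene may be listed under more than 1 symbol. Among ductal markers KRT19 and the carbonic anhydrase gene CA2 fell by 3.81 ± 0.43 and 3.06 ± 0.48, the transcription factor gene GATA6 rose by 1.75 ± 0.32 and SOX9 stood at -0.67 ± 0.19, 1 up and 3 down of 10 (3 and 3 adjusted over the list alone). Of the cancer stem cell markers, CXCR4, a chemokine receptor gene, rose from 1.26 to 60.2 CPM (5.63 ± 0.40), and CD24, a surface glycoprotein gene, fell from 167 to 3.55 CPM (-5.53 ± 0.29) and NES, which encodes nestin, from 340 to 6.37 CPM (-5.76 ± 0.42), 4 up and 4 down of 12 (6 and 5 adjusted over the list alone). The neuronal list was called higher, 3 up and 1 down of 8 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0458), with the synaptic vesicle gene SYT1 at 4.78 ± 0.29, the adhesion molecule genes NCAM1 and L1CAM at 4.44 ± 0.39 and -2.18 ± 0.29, and ENO2 at 1.85 ± 0.28. That call was lost with an estimated correlation, at an adjusted p of 0.657, with GC offsets (0.0633), with library sizes alone, with a filter at over 1 CPM in 3 libraries, and without any of the 6 libraries (0.0881 to 0.259). Of 7 fibroblast and stellate cell markers THY1 fell (-2.02 ± 0.27; 0 and 2 adjusted over the list alone), of 6 leukocyte and endothelial markers CD14 rose and ERG, named after its value was seen, fell (2 and 1 adjusted over the list alone), and of 3 acinar and endocrine markers 0 passed edgeR's test. Without PANC1OR replicate 3 the ductal list had 2 risen and 4 fallen, the stem cell list 7 and 5, the neuronal list 5 and 2, the fibroblast list 1 risen and 2 fallen, the leukocyte list 1 and 2, and the acinar list 1 and 1. The adjusted p of SOX9 was 0.115 to 0.182 without any 1 library other than PANC1OR replicate 3.

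**Figure D4:**
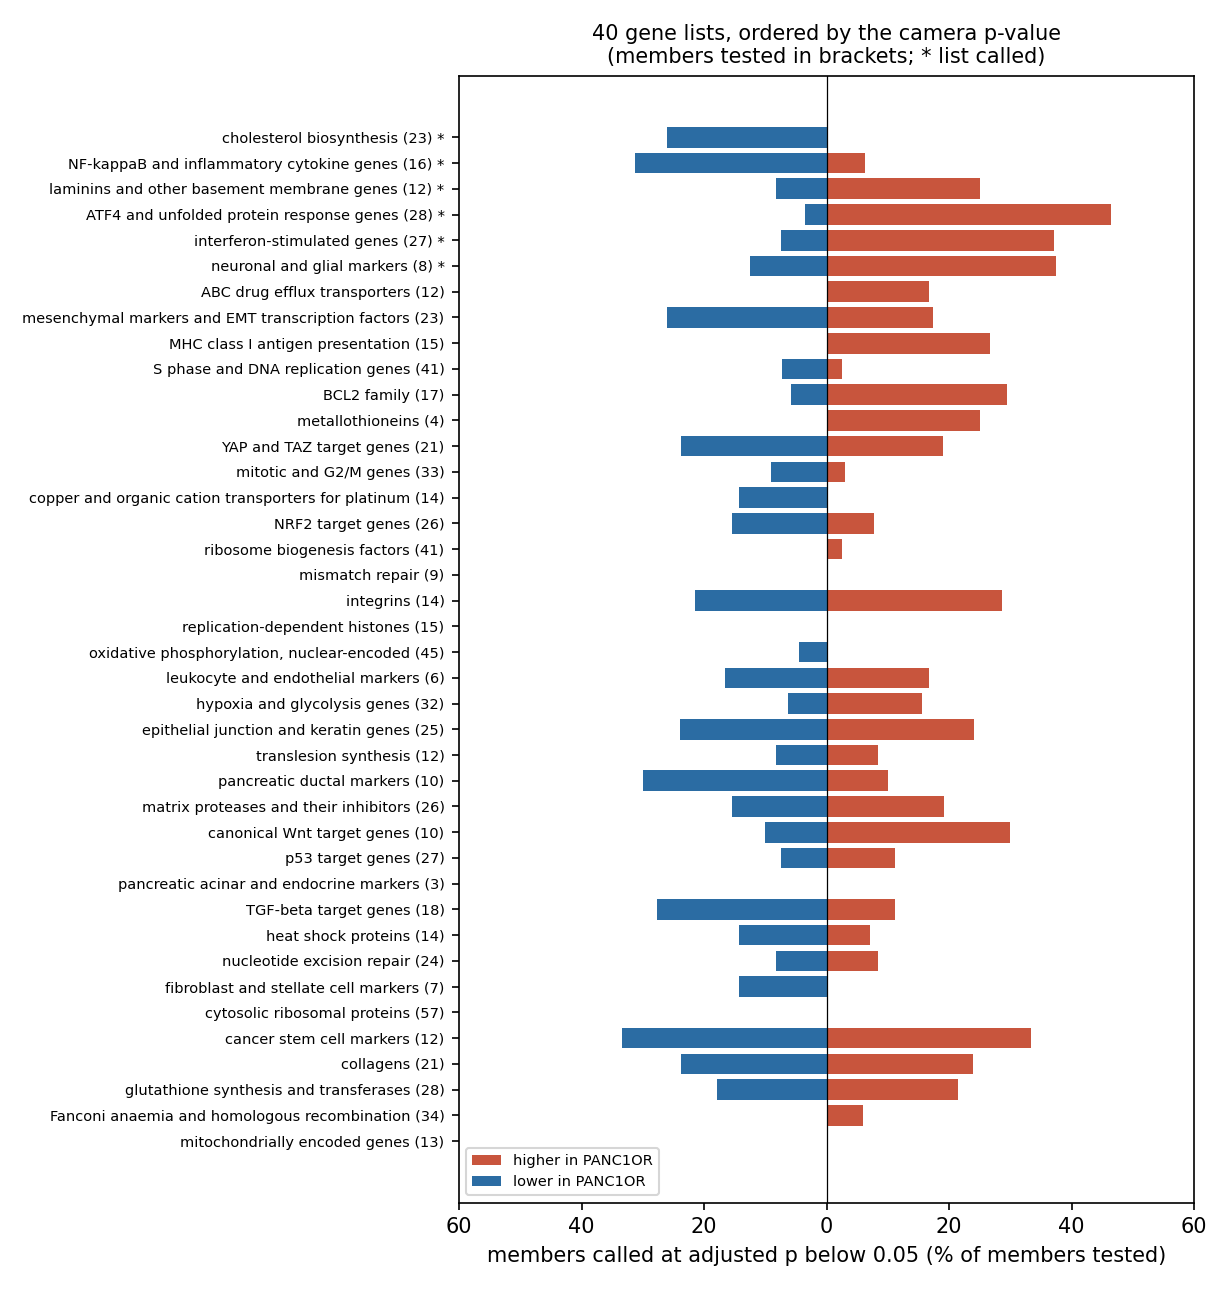
Percent of the tested members of each of 40 gene lists that were called higher (red, right of 0) or lower (blue, left of 0) in PANC1OR at an adjusted p under 0.05, with lists in order of their camera p-value and an asterisk on the 6 called lists. Cholesterol biosynthesis, at the top, had 0 risen and 6 fallen of 23 genes, and the ATF4 list had 13 risen and 1 fallen of 28.

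In all, 6 of 40 lists were called by camera, 4 higher and 2 lower, and 0 with an estimated correlation, where only the neuronal list had an unadjusted p under 0.05 (0.049). By fry, 6 lists passed, 3 in each direction. The lists of ABC transporters and mesenchymal markers passed fry (adjusted p of 0.0368 and 0.0308), and the laminin and ATF4 lists did not (0.0654 and 0.0755). The mean and median log2 fold change had opposite signs in the epithelial, YAP, Wnt, p53, heat shock, ductal and stem cell lists. In the fibroblast, Fanconi and mitochondrial lists both were positive while camera pointed lower, and for the collagen list fry pointed higher and camera lower.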

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

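The GC and length offsets, the joint removal of PANC1 replicate 2 and PANC1OR replicate 3, and for the chromosome blocks the GC offsets and the removal of PANC1OR replicate 3, were chosen after seeing the data. The 3345 genes called with 6 libraries kept their direction wherever they were called under every setting run. Counts stayed within 1.5 times under other scaling factors, the low-count filters, the likelihood ratio test, DESeq2 and limma-voom (3144 to 4281 genes, 1058 to 1659 past the cutoffs of the series design text). The neuronal list lost its call with library sizes alone and with a filter at over 1 CPM in 3 libraries, which left 5 lists each.

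Without 1 library, the count of changed genes ran from 1821 (without PANC1 replicate 3) to 8663 (without PANC1OR replicate 3, with all 3345 kept), the count past the cutoffs from 681 to 1544, and the number of lists from 1 (without PANC1OR replicate 3) to 5 (without PANC1 replicate 2 or PANC1OR replicate 2). Of the 185 genes named by the rule, 131 were called, 101 of them in each fit without 1 library and 131 with GC offsets. The cholesterol list was called in each of these fits.

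With GC offsets 7307 genes (3335 of the 3345) and 2 lists were called, with GC and length offsets 7583 genes and 3 lists, and without PANC1 replicate 2 and PANC1OR replicate 3 together 11422 genes and 2 lists. Fits without PANC1OR replicate 3 and without offsets keep a trend with GC content between the lines. Of the called genes 58.0% were higher with 6 libraries, 51.0% with GC offsets and 46.6% with GC and length offsets, so the balance of directions depends on the correction. GC offsets ended the calls of the NF-kappaB (adjusted p 0.125), interferon (0.125), laminin (0.0633) and neuronal lists (0.0633); the cause was not tested. At an adjusted p under 0.01, 1801 genes were called, and 1977 against a 1.5-fold change, both stricter by construction.

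With an estimated correlation 0 lists and 0 chromosome blocks were called. A simulated list changed by a log2 of 0.7 was called by camera in that setting (adjusted p 0.0215), but its genes were drawn independently of each other. In the 6 called lists the estimated correlation ran from -0.129 (neuronal) to 0.40 (laminins), so the simulation does not show how the setting treats such lists. The neuronal list, with a negative estimated correlation, went from an unadjusted camera p of 0.00686 to 0.049. The simulated list of independently drawn genes also had a far higher adjusted p in this setting than at the preset correlation (4.32e-18). A call lost in this setting therefore does not by itself show that correlated members made the call. The cause of the lost calls was not tested. With PANC1OR replicate 3 left out, which leaves a trend with GC content between the lines, 154 blocks were called against 85. The replicate number as a block gave 2324 genes and 3 lists, 1 higher and 2 lower, so the 3 lists that lost their call were among the 4 called higher. Deviations from the group mean of libraries with the same number correlated at 0.46, -0.45 and -0.22. PANC1 replicate 2 and PANC1OR replicate 3, which have different numbers but deviate the same way with GC content, correlated at 0.51. Since GC trends enter these values, they cannot show whether the numbers pair the cultures. The block also leaves fewer residual degrees of freedom, and how far this lowers the counts was not tested.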

Other observations

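Tests chosen only after the result was seen were those of genes outside the naming rule, of gene groups by symbol, of the GC and length trends in PANC1OR replicate 3, of chromosome blocks with GC offsets and between adjacent blocks, and of another cell line.

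Several ligands of the EGF family, ERBB3 and MET were higher in PANC1OR, beside HGF. These genes were picked after their values were seen, without a test of the group, and of 10 tested 7 rose and 1 fell. EREG, which encodes epiregulin, rose from 1.03 to 181.7 CPM (log2 fold change 7.44 ± 0.38) and AREG, which encodes amphiregulin, from 0.373 to 26.0 CPM (6.07 ± 0.38). BTC, which encodes betacellulin, had 0 reads in PANC1 and 80 in PANC1OR. EREG, AREG and BTC lie together on chromosome 4 between 74365145 and 74794523, so they are not independent members of the 7 that rose. The receptor gene ERBB3 rose by 3.03 ± 0.24 and the HGF receptor gene MET by 1.75 ± 0.23, and RET, which encodes the receptor of the GDNF family, fell from 52.0 to 0.914 CPM (-5.82 ± 0.24). EGFR and ERBB2 did not pass edgeR's test (adjusted p of 0.789 and 0.551). HBEGF rose by 0.80 ± 0.22, with an adjusted p of 0.04 that reached 0.191 without 1 library. Protein levels and receptor activity were not measured.

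Cancer-testis genes in a stretch of chromosome X from 152698767 to 152769716 were silent or nearly so in PANC1 and expressed in PANC1OR. MAGEA3 had 1 read in PANC1 and 187 in PANC1OR, and CSAG4 0 and 44, beside MAGEA6, MAGEA12 and CSAG1, while MAGEA4 went from 60 reads to 0. Reads of the MAGEA copies are not assigned with certainty, so the number of separate genes that rose is open. Protein-coding genes were also grouped by the letters that open their symbol, which gave 212 groups, not all of them gene families. Each was tested by Fisher's exact test against the other protein-coding genes tested. The protocadherin beta cluster fell in 6 of 8 genes (adjusted p = 0.00169) and genes with a collagen symbol in 9 of 29 (0.0286, with 6 risen). The latter are a wider set than the 21 of the fixed list, in which 5 rose and 5 fell. The protocadherin genes are neighbours in a block of chromosome 5 from 140245035 to 141619055 that was called lower (not with an estimated correlation), so they are not independent members and the p-value overstates the evidence. Zinc finger genes with a ZNF symbol were called less often than other protein-coding genes, 15 higher and 17 lower of 449 (adjusted p of 1.64e-07 and 0.0175 by Fisher's test). That test treats genes as independent and did not match them by expression level or GC content. Whether fewer calls follow from these was not tested.

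Some genes were off in 1 line, with at most 3 reads, and at 5 CPM or more in the other. There were 9 off in PANC1OR, ESX1, KCNJ2, KCNK10, LPAR3, MXRA5, NINJ2, SH3RF3, SORBS2 and TENM3, and 12 off in PANC1, which include the Toll-like receptor gene TLR4, the BMP antagonist gene GREM1, PALMD and DPF3. The 27 nearest expressed neighbours of the 9 genes had a median log2 fold change of -0.051 (95% bootstrap interval -0.473 to 0.265), so as a set they showed no common fall. The bootstrap treats neighbours of 1 locus as independent, and a median over several loci cannot exclude loss at single ones. Of these neighbours 6 stood at -1 or lower and 2 at 1 or higher, against 0 and 3 of the 21 neighbours of the genes off in PANC1. Loss of segments at single loci stays open, as do a smaller deletion, a change in regulation and selection of a pre-existing clone, which were not tested. Whether another cell line entered the PANC1OR cultures cannot be told apart from the difference between the lines: CDKN2A and CDKN2B had 0 reads in the PANC1OR libraries and 0 in PANC1, which excludes only lines that express these genes.

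Neighbouring genes moved together along chromosomes. Of 371 blocks of 50 genes, 39 were called higher and 46 lower in PANC1OR at the preset correlation and 0 with an estimated one. Without PANC1OR replicate 3, 78 were called higher and 76 lower at the preset one. Blocks called with all 6 libraries included that of chromosome 15 from 74954418 to 78552417 (0 risen and 21 fallen, median -0.88). They also included 2 adjoining blocks of chromosome 20 from 34450930 to 44752313 (21 and 18 risen, 0 fallen), and chromosome 5 had 8 of 17 blocks lower and 2 higher. The highest number of blocks in 100 shuffles of gene positions was 0. This argues against random placement and no more, since shuffles break any likeness of neighbours. With GC offsets 83 blocks were called, so the trends with gene GC content that the offsets remove were not the whole cause. The rule for this test compared with the shuffles, so any count above 0 would have passed it. Medians of adjacent blocks correlated at 0.723 (0.73 with GC offsets; highest of 1000 shuffles 0.385; other splits of the libraries 0.573 to 0.614), in line with gain or loss of long segments in 1 of the lines, for which no DNA was analysed here, and shared regulation of neighbours stays open. Other splits of the libraries gave up to 221 blocks, so the number of blocks alone does not set the lines apart. Each of these splits mixes the lines and so keeps part of their difference.

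PANC1OR replicate 3 differed from replicates 1 and 2 by a trend with GC content. Across 11490 genes the Spearman rho between its log2 difference and GC was 0.905 (genes are not independent replicates), and PANC1 replicate 2 differed from replicates 1 and 3 in the same direction at 0.508. GC and length offsets lowered the SD of its difference from 0.868 to 0.392, taking up 79.6% of the variance, against 0.142 between replicates 1 and 2. The smooth trends that the offsets remove thus did not take up all of the difference. The offsets use the GC content of 1 transcript per gene, so this cannot exclude GC content as the whole cause. The correlation with exon length was -0.0404 after GC offsets and -0.23 before, which argues against a length trend as broken RNA would give, but RN7SL RNA took 2.34% of its reads (0.321% and 0.553% in replicates 1 and 2; 1.33% in PANC1 replicate 2), MALAT1 1.06% (2.03% and 2.02%) and mitochondrial genes 5.24% (8.36% and 7.67%). A difference in RNA quality or library preparation, which may give such values, and a difference between the cultures stay open, since the labels give no batch.

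The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3345 changed genes and 1172 past the cutoffs of the series design text, each as large in 1 of the 10 splits, and the highest of the others was 0 for both. Each other split mixes the lines, so their difference becomes spread within groups, and low gene counts there were set by the design. These splits also keep part of the line difference, so their lists and blocks are not a baseline without it. For gene lists the real split gave 6 and the highest other 10, with 7 of the 10 splits at 6 or more. For chromosome blocks the real split gave 85 and the highest other 221, with 8 of the 10 splits at 85 or more. That highest split set PANC1 replicate 1 and PANC1OR replicates 1 and 2 against the others, which parts the libraries by their GC trends, and points to a structure of the samples in the blocks. It gave 6 lists, and with GC offsets the real split gave 2.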
